A study of Mus musculus with 8 samples.

How the data were processed

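RNA-seq was made from mouse corneas of 8 samples, each a pool of 4 corneas taken on day 14 of scopolamine injection, 4 samples with ICI 118551 (ICI) and 4 without (Scop). Per the labels' protocols, RNA was purified with a Qiagen RNeasy kit, libraries were made with a Vazyme VAHTS Universal kit, and sequencing was on an Illumina NovaSeq. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the mouse build mm10. Their versions and roles, the gene annotation, strandedness and the way rRNA was removed are not given in the sources used here. Whether reads of overlapping antisense genes were told apart is therefore unknown, and values of near-identical gene copies and of ribosomal RNA loci such as Gm26917 are uncertain.

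The authors deposited 1 table of FPKM values with a column per sample, and no scaling between samples is stated. Column sums lay between 434149 and 448239. Columns were matched to samples by their titles, which also gave group and replicate number. Gene names are those of the table, and coordinates are those of the RefSeq genes of the same build (GRCm38.p6), 1-based. The values of a gene lie on steps set by its length and the library's depth, so whole fragments were recovered from ratios between libraries. A ratio was read as a fraction of whole numbers within a relative tolerance of 5e-13, and a recovered value was taken as whole within 0.01. This gave whole fragments for 99.8% of genes and none for 57. Recovered totals lay between 34354346 and 39885822 per library, and matched the relative depths read from the commonest step ratio to within 0.0191%. A gene whose fragments share a factor in all libraries would be recovered too low by that factor. Low genes carry a large counting error, such as Cxcl2 with 3 fragments in ICI replicate 2.

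The test for single genes was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1), with the FPKM as deposited, over the 12100 genes with a mean of at least 0.5 FPKM. FPKM are not counts, so no count model gave the result. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and standard errors are limma's. It was tested on simulated data, fragments drawn gene by gene for 4 libraries per group with 11970 genes tested. There it called 17 of 50 genes changed by 1.25-fold, 37 of 49 by 1.5-fold, 44 of 48 by 2-fold and 50 of 50 by 3-fold, with 6 false calls. The list test called the 1 shifted list and 0 others. Real genes vary together, which the simulation left out. It also gave each gene the typical spread of genes of like abundance (a running median). Genes of larger spread were thus left out, and the shares found are too high for them.

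Of the gene lists, 40 were fixed before the data were examined, as were the tests and the first alternatives. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and with the variance trend, adjusted over the 37 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. A list's score is the mean log2(FPKM + 1) of its tested members in a library, and scores were compared by an exact permutation test added after the data had been seen. Some genes are in more than 1 list, such as S100a9, Thy1 and Cdkn1a. The fixed names of the mitochondrially encoded genes matched no gene, so the names in the table were used, as an addition.

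Named genes were chosen by a rule fixed before the data were examined. It takes, per direction, the 10 genes with the largest log2 fold change among those with an adjusted p under 0.05 and no overlap between the groups, without predicted models, filled up by the smallest unadjusted p where fewer pass. Since 0 passed, all were chosen by unadjusted p. It adds up to 4 members per list with the smallest p and a fixed set of genes of the cornea, inflammation, keratinisation, barrier and β-adrenergic receptors. Gm26917, AY036118, Lars2, Malat1, Kera, Lum, Dcn, Egr1, Crem, Pde4b, Per1, Clock, Bmal1, Hk2, Nfkb2, Casp1 and Il1rn fall outside it and were chosen after their values were seen. Some genes that the rule picks are not reported here, and they were left out of the search for outlying libraries after it had been run.

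The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-ratio scaling, scaling to a common sum, quantile normalisation, eBayes without trend or with robust estimation, array weights, other thresholds, the replicate number as a block, and leaving out each library. Limma-voom on the recovered fragments and a stromal score (the mean of keratocyte genes) as a covariate were added after the data had been seen. Pairs of libraries were checked for duplicates by a chi-square of their recovered fragments over genes, and the lowest value per degree of freedom was 13.1, so no pair differed by sampling noise alone.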

Results

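Messenger RNA was measured in corneas of mice with dry eye on day 14 of injections of scopolamine, a muscarinic antagonist. In 4 samples, named ICI, the mice had also received ICI 118551, an antagonist of the β2-adrenergic receptor, and 4 samples, named Scop, came from dry eye mice without it. Each sample held 4 pooled corneas. The labels do not say which mice gave which pool, so p-values measure only the spread between these 8 samples. The values were FPKM (fragments scaled by gene length and library depth), and 821 genes were at 0 in every library. The fragments counted per library, recovered from the steps of the FPKM values, lay between 34354346 (Scop replicate 3) and 39885822 (Scop replicate 1). No corneas without dry eye were among the samples, so each value below sets ICI against Scop and not against a normal cornea.

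Transcripts of the corneal epithelium were abundant in all 8 libraries. Krt12, the keratin of differentiated corneal epithelium, stood at 15846 ± 458 FPKM in ICI and 16258 ± 1467 in Scop (mean ± SD, n = 4 in each group, as for all FPKM below), and Aldh3a1, a corneal crystallin, at 10222 ± 307 and 10071 ± 373. Pearson correlations between libraries ran from 0.983 to 0.995, taken across genes, which are not independent replicates. The lowest involved Scop replicate 3, and without this library the lowest was 0.990. In Scop replicate 3 the keratocyte proteoglycan genes Kera, Lum and Dcn were at 39.0, 85.8 and 342 FPKM, below the lowest other libraries (163, 256 and 924). The keratin Krt16 and the envelope protein gene Sprr1a, both raised in stressed squamous epithelium, were at 77.1 and 58.2 FPKM there, above the highest other library (46.7 and 32.9, both Scop replicate 4). Gm26917 and AY036118, loci that collect reads of ribosomal RNA, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, separated the libraries in another way. Gm26917 lay between 3666 and 3836 FPKM in ICI, at 689, 912 and 1119.6 in Scop replicates 1, 2 and 3, and at 4936 in Scop replicate 4. The stromal, squamous and ribosomal examples were chosen after their values had been seen.

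**Figure D1:**
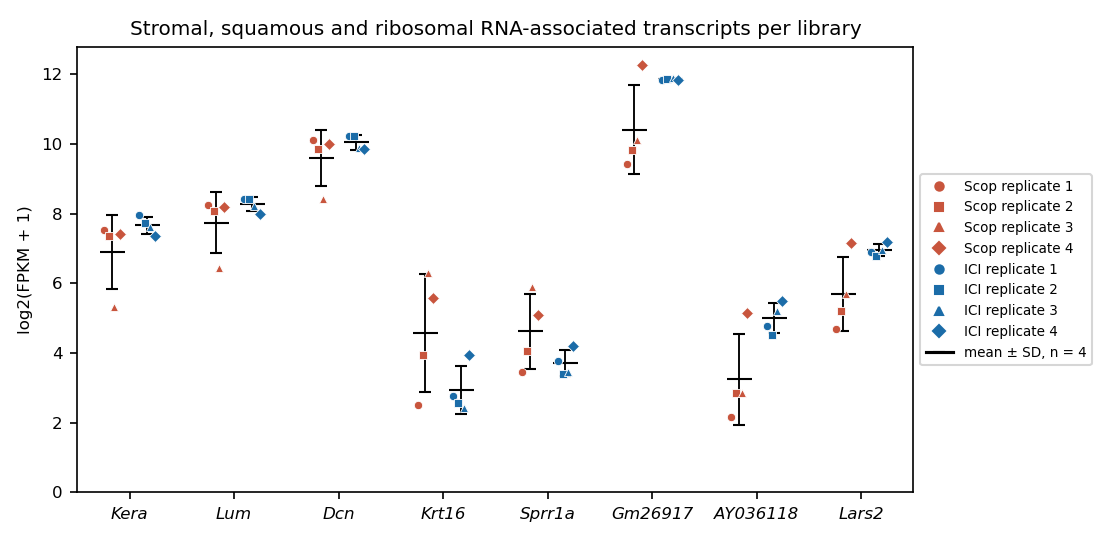
Log2(FPKM + 1) of stromal (Kera, Lum, Dcn), squamous (Krt16, Sprr1a) and ribosomal RNA-associated (Gm26917, AY036118, Lars2) transcripts in each library, with Scop in red, ICI in blue and black bars for mean ± SD (n = 4). Scop replicate 3 has the lowest Kera (39.0 FPKM) and the highest Krt16 (77.1 FPKM), and Scop replicate 4 lies with the ICI libraries for Gm26917 (4936 FPKM).

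The comparison of ICI with Scop asks which transcripts of the scopolamine-treated cornea differ when the β2-adrenergic receptor is blocked. Some transcripts of inflammatory genes were lower with ICI 118551, and the Toll-like receptor gene Tlr1 was higher (0.735 ± 0.105 against 0.267 ± 0.0931 FPKM, ICI against Scop). Cxcl2 and Cxcl1, chemokines that recruit neutrophils, were at 0.371 ± 0.266 against 2.89 ± 1.01 and 2.11 ± 0.475 against 5.05 ± 0.897 FPKM, and S100a9, an alarmin subunit, at 9.38 ± 2.35 against 20.3 ± 3.63. Tnfaip3 and Nfkbia, feedback inhibitors of NF-kB, were at 4.34 ± 1.37 against 8.29 ± 1.49 and 28.5 ± 2.71 against 37.7 ± 2.80 FPKM. Fkbp5, a glucocorticoid-induced co-chaperone, was also lower (36.5 ± 5.75 against 77.0 ± 29.2 FPKM), while the clock-controlled transcription factor gene Tef was higher (42.6 ± 3.39 against 31.8 ± 3.04 FPKM), and none of these genes passed the test adjusted over all 12100 genes. The NF-kB and cytokine lists passed a test with a preset inter-gene correlation, with the adjusted p = 0.187 and 0.361 with an estimated correlation.

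At an adjusted p under 0.05, limma counted 0 genes higher and 0 lower in ICI. At an unadjusted p under 0.05 it counted 1455 genes, 552 higher and 903 lower, where 605 are expected by chance. At the same unadjusted threshold genes higher in ICI numbered 674 after median-ratio scaling and 728 after quantile normalisation, and genes lower in ICI 745 and 717. Limma-voom on the recovered fragments counted 0 and 0 after adjustment, and 516 and 928 without it. The smallest adjusted p was 0.0788, shared by Cxcl2 (log2 fold change -1.49, SE 0.18), Cxcl1 (-0.96, SE 0.13), Cebpd (-0.85, SE 0.12), Esco2 (-0.51, SE 0.07), Capsl (0.49, SE 0.07) and Aldoc (0.52, SE 0.08). Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. With 1 library left out, the counts stayed at 0 except without Scop replicate 4, when Gm26917, AY036118, Lars2 and Malat1 passed as higher and Cxcl1 and S100a9 as lower, without Scop replicate 3 (Cxcl2 lower) and without Scop replicate 1 (Cebpd lower).

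Of the 10 genes with the smallest p among those lower in ICI, the 9 named here had all 4 ICI values below all 4 Scop values, and limma's adjusted p lay between 0.0788 (Cxcl2) and 0.154 (Dck), so all 9 failed. The neighbours Cxcl1 (chromosome 5, 90891245 to 90893121 of the mm10 build) and Cxcl2 (chromosome 5, 90903899 to 90905938) were both among them. Cxcl2 rested on 11, 3, 20 and 28 fragments in ICI replicates 1, 2, 3 and 4, and on 107, 93, 164 and 98 in the Scop replicates. Cebpd, a transcription factor gene of the acute-phase response (chromosome 16, 15887286 to 15889545), was at 3.64 ± 0.468 against 7.41 ± 1.30 FPKM. Esco2, an acetyltransferase for sister chromatid cohesion (chromosome 14, 65819027 to 65833969), was at 2.01 ± 0.184 against 3.30 ± 0.184 FPKM, and Tubg1, the γ-tubulin of microtubule nucleation (chromosome 11, 101119904 to 101126423), at 13.1 ± 1.12 against 17.8 ± 0.706. Dck, a kinase of nucleotide salvage, had a log2 fold change of -0.30 (SE 0.05). S100a9 (-1.04, SE 0.16), Ints10, a subunit of the Integrator complex (-0.34, SE 0.06), and Hr, a nuclear receptor corepressor (-0.49, SE 0.09), completed the 9.

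The 10 in the higher direction had all 4 ICI values above all 4 Scop values and failed as well (limma's adjusted p 0.0788 to 0.161). Aldoc, a glycolytic aldolase (chromosome 11, 78323073 to 78327781), was at 16.5 ± 0.299 against 11.3 ± 1.26 FPKM, Rbm3, a cold-inducible RNA-binding protein gene (chromosome X, 8138975 to 8145880), at 83.1 ± 6.53 against 64.4 ± 2.30, and Psca, a membrane-anchored surface protein gene (chromosome 15, 74714839 to 74717065), at 2825 ± 91.4 against 2340.2 ± 72.2. Selenov, a selenoprotein gene, was low, at 1.29 ± 0.169 against 0.619 ± 0.161 FPKM, as was Tlr1. Capsl, Ndrg4, Hebp1, Hacl1 and Gm2a had log2 fold changes of 0.49, 0.58, 0.40, 0.36 and 0.32. Of all tested genes 6.98% had no overlap between the groups, where chance gives 2.86% on average. Genes vary together, so a single grouping of the libraries can lie far from that average. The share was not counted for other groupings.

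**Figure D2:**
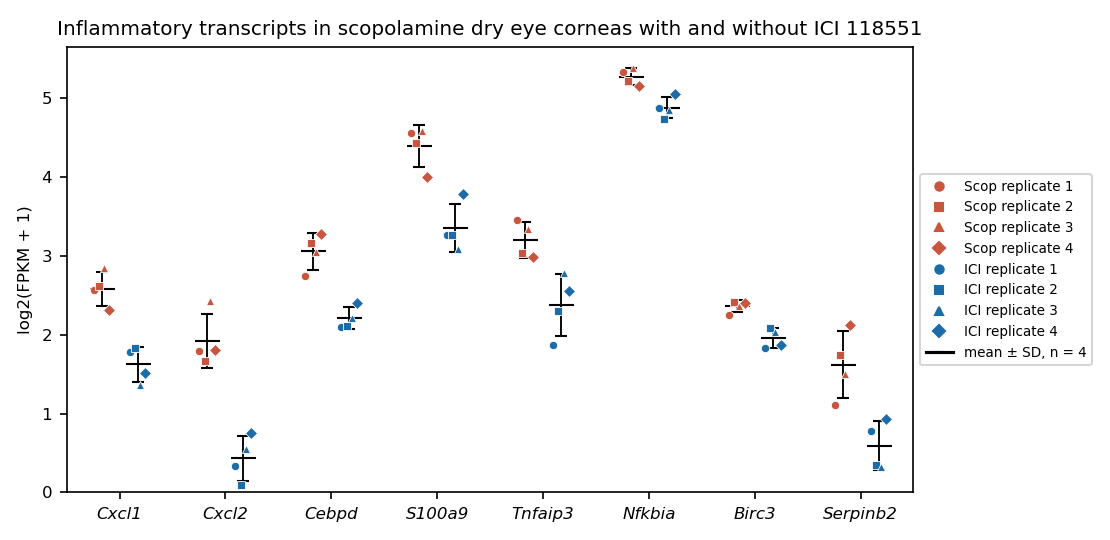
Log2(FPKM + 1) of Cxcl1, Cxcl2, Cebpd, S100a9, Tnfaip3, Nfkbia, Birc3 and Serpinb2 in each library, with Scop in red, ICI in blue and black bars for mean ± SD (n = 4). For each gene all 4 ICI values lie below all 4 Scop values, with log2 fold changes from -0.39 (Nfkbia) to -1.49 (Cxcl2).

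Of 40 gene lists fixed before the data were examined, 37 could be tested, and 8 passed limma's camera test with a preset inter-gene correlation, 5 as lower and 3 as higher in ICI. With an estimated correlation 0 passed, and 1 passed by fry, which asks whether a list's genes move on balance in 1 direction. The preset test called at least 8 lists in 23 of the 35 ways to split the 8 libraries into groups of 4, the real one included. No list member passed the test adjusted over all genes (0 in every list), and the counts of members below are adjusted over the list alone.

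The NF-kB and inflammasome list was lower in ICI. Adjusted over the list alone, 7 of its 22 tested members fell, 0 rose and 15 did not pass, against 0 over all genes, and 18 had negative values (median log2 fold change -0.12, camera adjusted p = 0.00112). The adjusted p = 0.187 with an estimated correlation, and 0.00303 by fry. The list's score lay lower in each ICI library than in any Scop library (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give). The members that fell were Nfkbia (-0.39, SE 0.08), Nfkbib (-0.24, SE 0.06) and Tnfaip3 (-0.82, SE 0.18), which restrain NF-kB, Birc3, an inhibitor of apoptosis (-0.40, SE 0.08), Nfkb2, a subunit of the factor (-0.29, SE 0.09), Casp1, the inflammasome protease (-0.50, SE 0.13), and Il1rn, the antagonist of the interleukin 1 receptor (-0.44, SE 0.14). Scop replicate 3 had the highest score of the 8 libraries, and without it the adjusted p was 0.0451.

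The list of inflammatory cytokines and chemokines was also lower, with 3 of 14 tested members down, adjusted over the list alone, against 0 over all genes, and 11 negative values (median -0.30, camera adjusted p = 0.00307). The adjusted p = 0.361 with an estimated correlation, and 0.0759 by fry. Cxcl2, Cxcl1 and Ccl7, a monocyte chemokine gene (0.259 ± 0.164 against 0.750 ± 0.347 FPKM), were the 3. Unlike Cxcl2 and Cxcl1, Ccl7 overlapped between the groups, with 15 fragments in ICI replicate 4 and 12 in Scop replicate 3. Ccl2, another monocyte chemokine gene, was at 0.502 ± 0.211 against 1.57 ± 1.55 FPKM, with 3.89 in Scop replicate 4 and at most 0.863 in the other libraries, and did not pass. Tnf and Il1a, genes of early inflammatory cytokines, had -0.37 (SE 0.20) and -0.34 (SE 0.13) without passing. Il1b and Il6 were too low to test, at 0.469 ± 0.155 against 0.375 ± 0.200 and 0.0392 ± 0.0639 against 0.0657 ± 0.117 FPKM. The score was highest in Scop replicate 3, without which the median was -0.15 and the adjusted p 0.0451, and with only genes of at least 5 FPKM it was 0.416.

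Of 20 tested wound and stress keratins and alarmins, 2 fell, adjusted over the list alone, S100a9 and the protease inhibitor gene Serpinb2 (0.537 ± 0.329 against 2.17 ± 0.921 FPKM), against 0 over all genes, and 18 did not pass (camera adjusted p = 0.661). The list's median of -0.02 was 0.02 without ICI replicate 4 and 0.04 without Scop replicate 3, when the test turned upward. S100a8, the partner of S100a9 in calprotectin, was at 1.10 ± 1.26 against 1.18 ± 0.631 FPKM. Its ICI mean rested on ICI replicate 4 (2.98), with the other ICI libraries between 0.389 and 0.644. Krt16 and Krt17, keratins of activated epithelium, were at 7.39 ± 4.71 against 35.7 ± 32.9 and 10.3 ± 3.20 against 20.6 ± 8.86 FPKM without passing, and both were highest in Scop replicate 3. In the list of cornified envelope and squamous keratinisation the envelope precursor gene Ivl fell (3.58 ± 0.345 against 5.03 ± 0.650 FPKM), 1 of 16 tested members (median -0.05, camera adjusted p = 0.595), and without Scop replicate 3 the test turned upward (adjusted p 0.950). Cnfn and Sprr1a, further envelope genes, had -0.96 (SE 0.30) and -0.92 (SE 0.44), again with the highest values in Scop replicate 3. Krt10, a keratin of skin, was at 0.534 ± 0.0913 against 0.596 ± 0.147 FPKM, and Sprr1b and Sprr2a3 did not exceed 0.169 and 0.156 FPKM in any library.

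Adrb1 and Adrb3, genes of β-adrenergic receptors, were at 2.98 ± 0.225 against 3.29 ± 0.133 and 0.758 ± 0.263 against 0.781 ± 0.195 FPKM. None of the 14 tested members of the adrenergic and catecholamine list passed (camera adjusted p = 0.595, median 0.04, but -0.01 without ICI replicate 1 and -0.05 without Scop replicate 3), among them Maoa, which degrades norepinephrine (0.13, SE 0.06), and Arrb1, an arrestin gene of receptor desensitisation (0.18, SE 0.09). The list of cAMP-responsive and immediate early genes was higher in ICI (median 0.24, camera adjusted p = 0.00307), and the adjusted p = 0.773 with an estimated correlation. None of its 22 tested members passed, and 14 had positive values. The list's score in ICI replicate 4 (3.77) lay within the Scop libraries (3.62 to 3.99), and without ICI replicate 1 the median was 0.16. The immediate early genes Egr1 and Fosb had 1.86 (SE 0.72) and 1.42 (SE 0.46). In ICI replicate 4 these 2 genes stood at 6.56 and 5.70 FPKM, within the Scop libraries (4.66 to 21.6 and 2.89 to 9.94). Fos ran from 32.6 to 164 FPKM among the ICI libraries and stood at 35.1 ± 3.99 in Scop. Nr4a1, a nuclear receptor gene induced by cAMP, was at 2.64 ± 1.83 against 1.35 ± 1.07 FPKM, and Crem and Pde4b, also induced by cAMP, had -0.06 (SE 0.09) and -0.19 (SE 0.12).

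Glucocorticoid targets were lower, with 4 of 14 tested members down and 0 up, adjusted over the list alone, against 0 over all genes (median -0.14, camera adjusted p = 0.0400). The adjusted p = 0.750 with an estimated correlation. The 4 were Fkbp5 (-1.01, SE 0.21), Tsc22d3, which encodes the leucine zipper protein GILZ (-0.66, SE 0.20), the metallothionein gene Mt1 (-0.24, SE 0.07) and the cell cycle inhibitor gene Cdkn1a (-0.17, SE 0.06). Fkbp5 reached 119 FPKM in Scop replicate 3, against 74.0 or less in the others. The list's call ended without ICI replicate 1, ICI replicate 2, Scop replicate 3 or Scop replicate 4 (adjusted p 0.121, 0.0975, 0.152 and 0.0666).

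The circadian clock list was higher in ICI (median 0.15, camera adjusted p = 0.00307), and the adjusted p = 0.750 with an estimated correlation. Of its 19 tested members 4 rose, adjusted over the list alone, and 0 fell, against 0 over all genes. Those that rose were Per2 (0.48, SE 0.10) and Per3 (0.31, SE 0.08), repressors in the clock loop, and the output transcription factor genes Tef (0.41, SE 0.08) and Dbp (0.63, SE 0.19). Clock and Bmal1, the activators of the loop, had -0.21 (SE 0.07) and -0.20 (SE 0.10) and did not pass, nor did Per1 (-0.39, SE 0.19). The list's score in ICI replicate 1 (3.38) lay within the Scop libraries (3.34 to 3.40), and without that library the median was 0.22. The arm of Per and Dbp differed from that of Bmal1 and Clock by 0.41, and by 0.18 with the score of Gm26917, AY036118 and Lars2 as a covariate.

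The proliferation list was lower (median -0.22, camera adjusted p = 9.4e-05), with negative values in 27 of 30 tested members and none passing. The adjusted p = 0.879 with an estimated correlation. Rrm2, a ribonucleotide reductase subunit gene (27.0 ± 3.29 against 36.1 ± 5.25 FPKM), Mcm5 and Mcm7, subunits of the replicative helicase (16.4 ± 3.12 against 22.8 ± 2.61 and 16.8 ± 3.33 against 21.9 ± 2.23), and Top2a, a DNA topoisomerase gene (12.1 ± 1.96 against 16.2 ± 2.01), had the smallest p. The score ran from 3.04 to 3.58 within ICI and was highest in Scop replicate 3 (3.68). Without Scop replicate 3 the median was -0.13 (adjusted p 0.0107), and without ICI replicate 2, which had the lowest score, -0.12 (adjusted p 0.0164). The list of unfolded protein and osmotic stress was lower as well (median -0.18, camera adjusted p = 0.000725), with 18 of 21 values negative and 4 passing over the list alone. The adjusted p = 0.750 with an estimated correlation. The 4 were the chaperone genes Hsp90aa1 (-0.28, SE 0.07) and Hsp90b1 (-0.31, SE 0.10) and the endoplasmic reticulum stress genes Creld2 (-0.38, SE 0.10) and Sdf2l1 (-0.38, SE 0.10).

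**Figure D3:**
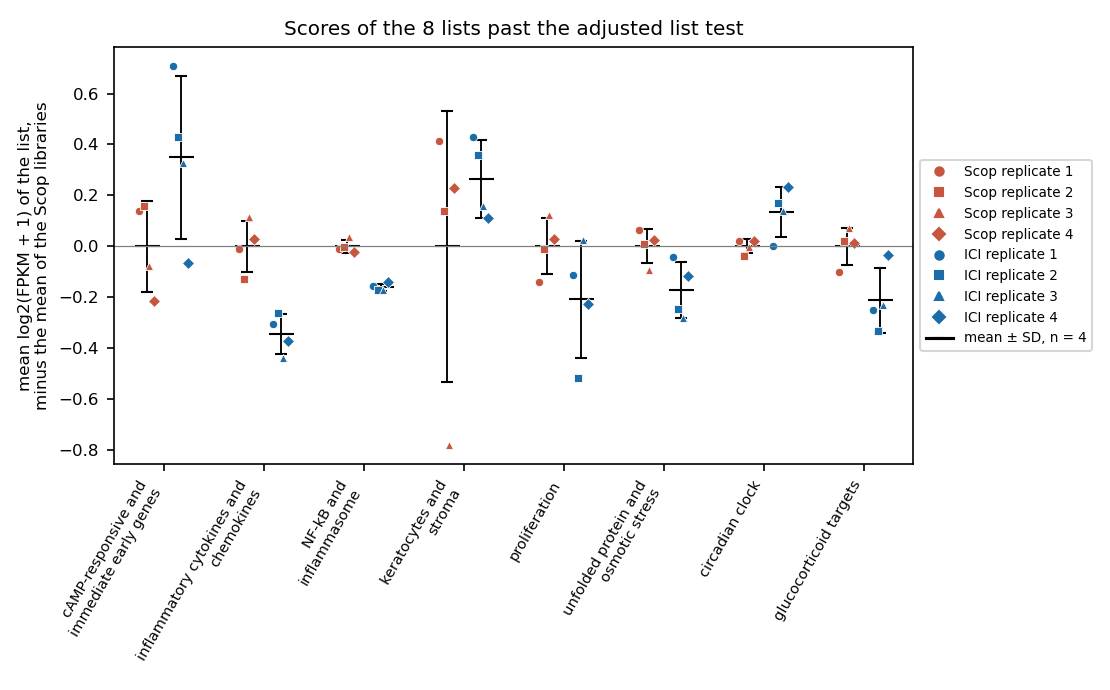
Mean log2(FPKM + 1) of the tested members of each list past the camera test with the preset correlation, minus the mean of the Scop libraries, in each library, with Scop in red, ICI in blue and black bars for mean ± SD (n = 4). All ICI libraries lie below all Scop libraries for the NF-kB list and the cytokine list, and Scop replicate 3 lies far below the other libraries for the stroma list.

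Keratocyte and stromal transcripts were higher in ICI by the preset test (median 0.34, camera adjusted p = 0.00126), with positive values in 22 of 25 tested members. The adjusted p = 0.879 with an estimated correlation, and without Scop replicate 3 the median was 0.05 and the adjusted p 0.357. Within the list the fibronectin gene Fn1 rose (43.5 ± 2.84 against 32.5 ± 4.79 FPKM) and Thy1, a surface protein gene of fibroblasts and T cells, fell (0.549 ± 0.159 against 1.34 ± 0.335), adjusted over the list alone. The collagen genes Col1a1 and Col1a2 had 0.54 (SE 0.29) and 0.59 (SE 0.32), and 0.23 and 0.22 without Scop replicate 3. The myofibroblast list did not pass (camera adjusted p = 0.718), and Acta2, its smooth muscle actin gene, was at 0.988 ± 0.527 against 1.31 ± 0.415 FPKM. Corneal endothelium did not pass either (adjusted p 0.404), and its genes Slc4a11, a transporter, and Car3, a carbonic anhydrase, were at 41.4 and 285 FPKM in ICI replicate 1 against at most 16.1 and 87.2 in the other ICI libraries.

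The list of corneal epithelial identity had a median of -0.06 (camera adjusted p = 0.0818), and 1 of 21 tested members fell, adjusted over the list alone, the connexin gene Gjb2 (48.3 ± 1.92 against 56.8 ± 2.90 FPKM). Without Scop replicate 3, which had the highest score, the median was -0.02 and the adjusted p 0.950, and the list was called without ICI replicate 3 or 4 or Scop replicate 1 or 2 (0.0483, 0.0431, 0.00924 and 0.0182). Pax6, the regulator of eye development, was at 160.0 ± 10.2 against 165 ± 6.52 FPKM, and Krt14, a basal keratin, at 265 ± 38.5 against 359.7 ± 156, highest in Scop replicate 3 (553). Krt12 had -0.03 (SE 0.07), and 0.01 after quantile normalisation. None of 29 tested junction and barrier genes passed (adjusted p 0.253), and the list was called as lower without ICI replicate 3 or Scop replicate 1 or 2 (0.0483, 0.0484 and 0.0182) but turned upward without Scop replicate 3 (0.950), with the tight junction genes Tjp1 and Ocln at 31.7 ± 1.48 against 31.1 ± 2.07 and 18.8 ± 1.04 against 17.9 ± 1.16 FPKM. None of 12 mucin and glycocalyx genes passed (adjusted p 0.629), among them the mucin-glycosylating enzymes Galnt1 (-0.17, SE 0.06) and Galnt3 (-0.19, SE 0.07). Matrix metalloproteinases did not pass (adjusted p 0.815), with Mmp3 at 21.0 ± 10.4 against 22.0 ± 2.69 FPKM and Mmp9 too low to test (0.0302 ± 0.0310 against 0.0309 ± 0.0214). Plaur, the urokinase receptor gene of the same list, had -0.59 (SE 0.16) without passing. Goblet and conjunctival genes (0.595), with the keratins Krt19 (-0.31, SE 0.12) and Krt4 (-0.34, SE 0.14), and lacrimal and meibomian gland genes (0.205), with the lipid droplet gene Plin2 (-0.27, SE 0.09), did not pass, though the gland list was called without ICI replicate 3 or Scop replicate 2 (0.0239 and 0.0406).

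Immune cell lists did not pass. The adjusted p was 0.404 for neutrophils, of whose 21 members 5 could be tested, and S100a9 was the member that fell. It was 0.404 for macrophages and monocytes (14 of 23 members tested) and 0.661 for dendritic cells and MHC class II (8 of 20). For T and NK lymphocytes, of whose 30 members 3 could be tested, it was 0.739. Adjusted over that list alone, 1 member rose and Thy1 fell. H2-Aa, an MHC class II chain, was at 5.68 ± 1.02 against 4.97 ± 1.81 FPKM, and Cd68, a macrophage marker, at 10.4 ± 1.34 against 9.42 ± 0.501. Cd3e, a T cell marker, did not exceed 0.132 FPKM in any library. Of the mast and B cell list 2 genes could be tested, Kit and Cd79b (0.02, SE 0.06 and 0.12, SE 0.13), too few for a list test. None of 30 interferon-response genes passed (adjusted p 0.595). The list was called as lower without ICI replicate 2 or Scop replicate 4 (0.00131 and 0.00241) and turned upward without ICI replicate 3 or 4 or Scop replicate 1 or 3, and their score varied from 2.94 to 3.86 within ICI and from 2.98 to 3.95 within Scop.

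Of 23 glycolysis and hypoxia genes 6 rose and 2 fell, adjusted over the list alone, against 0 over all genes (camera adjusted p = 0.0716). Among those that rose were the glycolytic gene Gapdh (59.0 ± 5.03 against 49.0 ± 2.91 FPKM), Pdk1, a brake on pyruvate oxidation (18.7 ± 1.56 against 15.0 ± 0.921), and Bnip3, a hypoxia-induced mitophagy gene (4.51 ± 0.716 against 2.57 ± 0.844), and those that fell were the hexokinase gene Hk2 (-0.24, SE 0.08) and the peptide hormone gene Adm (-0.38, SE 0.08). The call of this list was gained without ICI replicate 2, ICI replicate 4 or Scop replicate 3 (adjusted p 0.0116, 0.0334 and 0.0137). Nuclear-encoded oxidative phosphorylation (0.702), apoptosis and p53 targets (0.959), and lipid and cholesterol synthesis (0.253) did not pass, though the last was called as lower without ICI replicate 3 or Scop replicate 2 (0.000797 and 0.0218). Nrf2 and oxidative stress targets had an adjusted p of 0.954, with a median of 0.02 against a mean of -0.03 and a downward test that turned upward without ICI replicate 1 or 2 or Scop replicate 3, and the reductase gene Txnrd1 fell within that list (-0.42, SE 0.10). Cytosolic ribosomal proteins had an adjusted p of 0.494, with a median of -0.00058 against a mean of 0.01 and an upward test that turned downward after quantile normalisation and without ICI replicate 4 or Scop replicate 1, and that was called without Scop replicate 2 (adjusted p 0.00217).

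Lists of nerve and neighbouring tissues did not pass. The adjusted p was 0.258 for neurotrophic and nociceptive genes, with the neurotrophin gene Ntf3 (0.12, SE 0.06), and 0.661 for Schwann cells, in which the myelin gene Pmp22 fell over the list alone (-0.19, SE 0.05). It was 0.404 for lens and retina, in which the small heat shock protein gene Cryab rose over the list alone (0.30, SE 0.08), 0.606 for iris and pigment cells, 0.608 for vessel endothelium and 0.758 for skeletal muscle, a list whose direction turned under another scaling. For blood it was 0.595, with a median of -0.04 and a mean of -0.03 against an upward test, and the median was positive without ICI replicate 1, 3 or 4 or Scop replicate 1 (0.09, 0.05, 0.03 and 0.19). The mitochondrially encoded genes, all 13 tested under the names in the table, had a median of 0.07 and an adjusted p of 0.419. Of the sex-linked list Xist could be tested (27.5 ± 3.48 against 26.4 ± 4.26 FPKM).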

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

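The tests on macrophages, on the ribosomal transcripts, on clock phase, on Scop replicate 3 and on the number of lists called were chosen after the results were seen, and those on 7 single lists after that number was known. Of 414 groups of 4 libraries, 31 had a library far from the other 3, where chance gives about 1 in 20 (20.7).

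In ICI replicate 1 the scores of corneal endothelium (5.72) and of myofibroblasts (3.61) and the FPKM of Car3 (285), Slc4a11 (41.4), Krt18 (4.45) and Myoc (8.40) lay above the other ICI libraries. Capsl (4.40) and Adrb3 (0.369) lay below them there. In ICI replicate 2 the scores of blood (1.57) and of T and NK lymphocytes (1.54) and the FPKM of Hbb-bs (2.17), Thy1 (0.786), Hacl1 (4.22) and Adrb1 (3.32) were high, and Ints10 (8.02) was low. In ICI replicate 3 the Nrf2 score (5.57) and Pmp22 (16.5) were high and Ccl2 (0.189) was low. In ICI replicate 4 S100a8 (2.98), Krt16 (14.4) and Trp63 (58.6) were high and Cdkn1a (98.1) was low.

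In Scop replicate 1 the blood score (1.63) and Hbb-bs (2.62) were high and Capsl (3.16) was low. In Scop replicate 3 Cxcl2 (4.39) and Galnt3 (50.8) were high and Creld2 (21.0) and Rps14 (1510.0) were low. In Scop replicate 4 Ccl2 (3.89) was high and Bfsp1 (1.82) was low.

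The NF-kB and chemokine genes chosen because they fell over their lists alone, 10 in all, had a median log2 fold change of -0.45, and -0.39 without Scop replicate 3. For these 10 genes, a different share of stromal RNA as the whole cause is argued against. Their median was -0.3739 with the stromal score as a covariate. This score was lowest in Scop replicate 3 (5.13), and the genes had been chosen because they fell. Over the whole lists the medians with this covariate were -0.10 for NF-kB and -0.16 for cytokines. Fewer macrophages in the ICI pools as the whole cause are argued against for these 10 selected genes only. The macrophage score was 0.05414 higher there (SE 0.11), far from -0.45. The whole lists had medians of -0.12 (NF-kB) and -0.30 (cytokines). For the whole NF-kB list the SE is too large for this test to decide. Scop replicate 3 had the lowest macrophage score (1.73), and without it the median of the macrophage list turned to -0.03. A library difference marked by Gm26917, AY036118 and Lars2 cannot be told apart from the treatment, because only 1 Scop library lay on the ICI side of their score, though the median was -0.5434 with that score as a covariate. The splits were also run for 8 lists, all called in the real split, the NF-kB list among them. For the NF-kB list 1 of 35 splits, the real one, gave a camera p as small as 9.08e-05, and the smallest other was 0.0003396. This is the smallest share that 35 splits can give, with no adjustment for the 8 lists, so chance could not be excluded. The treatment with ICI 118551 stays among the open explanations, as untested apart from the library difference.

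In Scop replicate 3 the tested members of the keratocyte and stroma list had a median log2 deviation of -1.157 from the other libraries. The library's depth differed by -0.17 (log2), far less than these deviations, which had an SD of 0.56. FPKM are already scaled by depth, so a shallower library alone would not shift them, and this comparison tests little. A smaller share of stromal tissue may account for the low values. A share of 0.84 of the members (21 of 25) lay lower by over 0.5, which fell between the bounds set for and against this explanation. Those bounds and the set of genes were chosen after the low stromal values had been seen, and the lower bound was moved when the set was widened from the keratocyte genes of the stromal score to the whole list. This stays open, and no biological explanation was tested.

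Clock genes differed in sign, the Per, Dbp and Rev-erb arm (10 genes) by 0.24 (SE 0.10) and the Bmal1 and Clock arm (4 genes) by -0.16 (SE 0.06). A different share of stromal RNA is argued against, since the difference of 0.4063 between the arms was 0.4449 with the stromal score as a covariate. For a difference in clock phase, such as another hour of dissection, nothing was tested beyond the opposite signs that raised it, and the exact permutation p of the difference was 0.0571. The library difference marked by Gm26917, AY036118 and Lars2 may account for it, as the difference was 0.1807 with that score as a covariate. Only 1 Scop library lay on the ICI side of that score, so this smaller value cannot tell the library difference from the treatment. The library difference, the phase and the treatment stay open.

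The splits cannot test the real count of 0 genes passing the adjusted test, since 35 of 35 give at least 0 (highest other 1). Chance could not be excluded for the other counts, nor for any of the 8 lists. For genes with an unadjusted p under 0.05, 2 splits gave at least the real 1455 (highest other 1495, with ICI replicate 1 and Scop replicates 1, 2 and 4 on a side). For the number of lists called, 23 splits gave at least the real 8 (highest other 15). A camera p as small as the real one came from 5 splits for the cytokine list (real 0.000416, smallest other 6.398e-07), 5 for the cAMP list (0.000528, 1.81e-07), 5 for the clock list (0.000580, 1.549e-07) and 4 for the unfolded protein list (3.92e-05, 4.284e-06). It came from 9 splits for glucocorticoid targets (0.00865, 3.793e-06), 13 for proliferation (2.54e-06, 7.164e-20) and 17 for stroma (0.000137, 1.215e-14). The estimated inter-gene correlation was 0.458 for proliferation and 0.728 for stroma, above the preset 0.01. It was 0.0315 for cytokines and -0.00517, below the preset, for NF-kB. For the other lists called it lay between 0.0835 (glucocorticoid targets) and 0.186 (unfolded protein). The cause of the calls in other splits was left open.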

How the results depend on the processing

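The voom, stromal covariate and mitochondrial settings were chosen after the data were seen. Counts of 0 genes higher and 0 lower held under both pseudocounts, both filters, 3 scalings, eBayes without trend or robust, the replicate block and limma-voom. Array weights gave 3 higher and 4 lower, the stromal covariate 0 and 1, an adjusted p under 0.1 2 and 4, and an unadjusted p under 0.05 with a 2-fold change 6 and 6. With 1 library left out the counts ran from 0 to 4 higher and from 0 to 2 lower, both highest without Scop replicate 4. The causes were not tested.

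Lists called numbered 8, between 7 (without ICI replicate 1 or Scop replicate 3) and 13 (without Scop replicate 2) with 1 library left out, 12 with no filter, 1 with fry and 0 with an estimated correlation. With an estimated correlation the adjusted p was 0.7733 for the cAMP list, 0.3608 for cytokines, 0.1872 for NF-kB, 0.8789 for stroma and for proliferation, and 0.7502 for unfolded protein, clock and glucocorticoid lists. By fry it was 0.526 for cAMP, 0.07587 for cytokines, 0.675 for stroma, 0.5187 for proliferation, 0.3093 for unfolded protein and for glucocorticoid targets, and 0.4004 for the clock.

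Among genes of at least 5 FPKM the adjusted p was 0.4157 for cytokines, of which 4 genes were left, and 0.1248 for the list glucocorticoid targets. For that list it was 0.057 without trend, 0.0922 with array weights and 0.4355 with the stromal covariate, and from 0.002697 (without ICI replicate 4) to 0.1518 (without Scop replicate 3) with 1 library left out. For the list keratocytes and stroma it ran from 3.292e-05 (without Scop replicate 4) to 0.3574 (without Scop replicate 3), and with the stromal covariate, which shares its genes, the direction turned (0.9863). The NF-kB list kept its direction and call in 21 of 22 alternatives, with adjusted p from 2.872e-05 to 0.1872. Over all alternatives the adjusted p ran from 0.000446 to 0.416 for cytokines, 1.46e-05 to 0.773 for cAMP, 2.41e-06 to 0.986 for stroma, 5.13e-09 to 0.879 for proliferation, 2.28e-05 to 0.750 for unfolded protein, 9.66e-05 to 0.750 for the clock, 0.00270 to 0.750 for glucocorticoid targets and 0.00843 to 0.879 for glycolysis. Glycolysis gained a call in 9 of 22, corneal epithelial identity in 6, junctions, glands and lipid synthesis in 3 each, the list interferon response in 2 (0.001307 without ICI replicate 2, 0.002406 without Scop replicate 4) and the list cytosolic ribosomal proteins in 1 (0.002173 without Scop replicate 2).

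Robust estimation could not be run for lists. T and NK lymphocyte, vessel, lens, iris, muscle and blood lists had too few genes of at least 5 FPKM. Correlations of same-numbered ICI and Scop libraries' deviations were 0.287, -0.00927, 0.138 and 0.0769, and ICI replicates 1 and 3, but not 2 and 4, correlated best with their own number, so the numbers were not taken to pair the libraries. With the replicate block 0 genes were higher and 0 lower, and 8 lists were called. Depth limits low genes such as Cxcl2 and Ccl7.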
